A study of Drosophila melanogaster with 4 samples.

How the data were processed

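RNA from BG3 cells, a Drosophila melanogaster line derived from the larval central nervous system, was sequenced after RNA interference against Cap-H2 or against bw (Brown), an eye pigment gene used as the control target. Per the labels' protocols, cells in medium with serum and insulin were incubated with 20 µg of dsRNA for 30 min and cultured for 4 days, RNA was extracted with phenol and chloroform, and libraries were made with a stranded mRNA kit. Each group held 2 libraries. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

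The submitters' processing notes name fastp, HISAT2 and HTSeq and the genome build dm6, with the versions, the annotation and the strand setting of the counting not given in the sources used here. The main table held normalized read counts, a signal that the authors deposited for each library. Its values were read counts divided by a size factor per library. The tool behind the size factors is not given in the sources used here. Dividing each column by its smallest step returned whole reads for 100% of values at a tolerance of 0.001 reads. The table held 8806 rows of genes and transposable element families and 3 special rows of HTSeq, for reads with no feature, ambiguous reads and alignments that were not unique. The special rows, which took between 11.5% and 13.9% of all reads in the table, stayed out of library sizes and tests. Without them the control libraries 1 and 2 held 21682729 and 21539511 reads and the knockdown libraries 1 and 2 held 21935781 and 21762964, and the smallest row had 10 reads over the 4 libraries. A second table held the authors' deposited log2 fold changes with their errors, and the authors' unadjusted and adjusted p-values. Its fold changes were far smaller than the ratios of group means for most genes, so they were quoted only as the authors' values and not set against fold changes computed here.

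Rows were matched to the Ensembl annotation BDGP6.54, which uses dm6 coordinates. Of the 8806 rows, 8649 matched by symbol, 37 by a synonym and 106 were element families (59 LTR, 31 non-LTR and 16 DNA families), while 14 had no match. The control target bw was not analysed here, since no row was matched to it.

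The comparison was tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean trend, two-sided) on log2 of the normalized count plus 1, for the 7690 rows with a mean of at least 10 over the 4 libraries. Fold changes are on this scale, which understates the change of low genes. The 1116 rows under the minimum were left out. Calls were made at a Benjamini-Hochberg adjusted p of 0.05. Residual degrees of freedom were 2, and limma's prior contributed 14.4. With a library left out fewer remain, so p-values of those fits rest mostly on this prior, which is pooled over genes. An exact permutation test of 2 against 2 cannot go below p = 0.333, so no call here rests on permutation. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 35 lists, with fry and an estimated correlation as alternatives, and the same test was run on chromosome arms. Adjustment was over the 7 sets for arms and pericentromeric genes, the 4 element sets and the 4 lists added later, each apart from the 35. The preset correlation treats the genes of a list as nearly independent. The estimated correlation leaves camera only the 2 residual degrees of freedom, and its smallest adjusted p over the 35 lists was 0.52. A list that did not pass with it was therefore not shown to owe its call to correlated genes.

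The design, the threshold, the 35 lists, the rule for named genes and the main alternatives were fixed before the data were examined. The rule named the condensin subunits, up to 10 called genes per direction with the largest fold change and with the groups not overlapping and a mean of at least 50 in the higher group, the 3 members with the smallest p of each called list, 1 member of any other list with a called gene, and the most abundant member of each of 7 cell type lists. Element families, 4 further lists, the exonic length correction and edgeR with a replicate block were added after the data were seen.

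Alternatives were pseudocounts of 0.5 and 5, no minimum and a minimum of 50, median centring, TMM factors, quantile normalization, robust empirical Bayes, a replicate block, leaving out each library, and count models on the recovered whole reads (edgeR 4.0.16, quasi-likelihood, and DESeq2 1.42.0). On the whole reads edgeR called 28 genes and DESeq2 45. DESeq2 gave no adjusted p for 6112 of the 7690 rows, so it could not call those and adjusted over the other rows only. The common biological coefficient of variation was 0.0355 in edgeR. No pair of libraries was a duplicate: chi-square over degrees of freedom ranged from 2.97 to 7.96 over the library pairs, with the 2 control libraries at 5.08 and the 2 knockdown libraries at 2.97. Control library 2 was nearer to the knockdown libraries (4.12 and 4.27) than to control library 1, which stood at 6.61 and 7.96 from them. Without element and ribosomal RNA rows the control libraries differed by 3.39, control library 2 from the knockdown libraries by 3.32 and 3.08, and control library 1 from them by 3.34 and 5.19.

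The fits were tested on simulated counts for this comparison, with 7690 genes of which 200 with a mean of at least 200 were changed. Each simulated gene varied as the edgeR trend gives for its level, without the further spread between genes that real data hold. The shares recovered and false can therefore be too favourable. The limma fit recovered 65.7% of the genes changed 1.2-fold, and 100% of those changed 1.5-fold and 2-fold, with 4.84% of its calls false. Of 500 simulated lists of unchanged, independent genes, 0.4% had a camera p under 0.05. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.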

Results

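The transcriptome of BG3 cells treated with dsRNA against Cap-H2 was compared with that of cells treated with dsRNA against Brown. The question was how gene expression differs after Cap-H2 knockdown. Condensin II is a protein complex that compacts chromosomes, and Cap-H2 is a subunit of it. Each group held 2 libraries, with between 21539511 and 21935781 reads on genes and element families per library. Reads of copia, an LTR retrotransposon, made up 22.5% ± 0.204 (SD, n = 2) of these reads in the control and 23.7% ± 0.119 (SD, n = 2) in the knockdown. Ribosomal RNA rows took 31210 reads in control library 1 against 8855 in control library 2, and 6815 and 11826 in knockdown libraries 1 and 2.

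Cap-H2 itself (FBgn0037831, dm6 chromosome 3R, 10761310 to 10766756, plus strand, a protein-coding gene) fell to 62.7% of the control. Its normalized read counts were 880 and 873 in the control libraries and 543 and 555 in the knockdown libraries, that is 876 ± 4.53 against 549 ± 8.42 (SD, n = 2 each). The log2 fold change was -0.67 (SE 0.06), with limma's adjusted p = 1.5e-05. The reduction was therefore partial and seen at the RNA level only, since these data do not measure Cap-H2 protein or condensin II. Exons of Cap-H2 share 333 of 4087 bp with an antisense RNA and 135 bp with TfIIFbeta on the opposite strand, and whether the counting used strand is not given in the sources used here.

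None of the other 6 condensin subunits passed the limma threshold, and 2 of them, SMC2 and Cap-D3, had both knockdown libraries below both control libraries. SMC2, an ATPase shared by condensin I and II, had a log2 fold change of -0.11 (SE 0.04, adjusted p = 0.55), and Cap-D3, a condensin II subunit, of -0.10 (SE 0.07, adjusted p = 0.75). Leaving out a library gave values from -0.16 to -0.05 for SMC2 and from -0.14 to -0.06 for Cap-D3, both ends without a knockdown library. The other values were -0.04 for Cap-G, -0.03 for glu, -0.03 for barr and -0.02 for Cap-D2, with adjusted p from 0.83 to 0.95. Without control library 1 the values of glu, Cap-G and barr turned to 0.01, 0.00 and 0.01, and without control library 2 that of Cap-D2 turned to 0.00. The list of 7 condensin subunits was lower by camera (median log2 fold change -0.04, adjusted p = 0.00061), with 1 member past the threshold over all genes and 1 adjusted over the list alone, and adjusted p = 0.61 with an estimated correlation. The dsRNA target is a member of this list, so its call is not independent of the design. Without Cap-H2, a list formed after the calls were seen, the other 6 had a median of -0.04 and did not pass camera when adjusted together with the 35 lists (adjusted p = 0.064). Adjusted over the 4 lists added after the data were seen, the p was 0.042 (adjusted p = 0.26 with an estimated correlation), and 0.31 without control library 1, 0.14 without knockdown library 2 and 0.071 with median centring. Without control library 2 the median of the 7 was -0.09, and with median centring -0.03.

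Across the transcriptome 30 of 7690 tested genes and element families passed, 25 higher and 5 lower in the knockdown. All 30 changed by less than a log2 fold change of 1, from -0.67 to 0.92, and in all 30 the libraries of the groups did not overlap, which held for 38.7% of all tested rows and holds for 33.3% by chance. The largest increases were in CG9521, CBP, Sirup and CG34330, and next to Cap-H2 the decreases were in fat-spondin, Ect3, GstS1 and regucalcin. An unadjusted p under 0.05 was found for 625 rows. Leaving out a library, where the lone library is assumed to vary like the other group, gave 74 calls without control library 1, 127 without control library 2 and 68 without knockdown library 1, with 28, 30 and 28 of the 30 among them. Without knockdown library 2 there were 43 calls with 24 of the 30, and quantile normalization left 14.

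**Figure D1:**
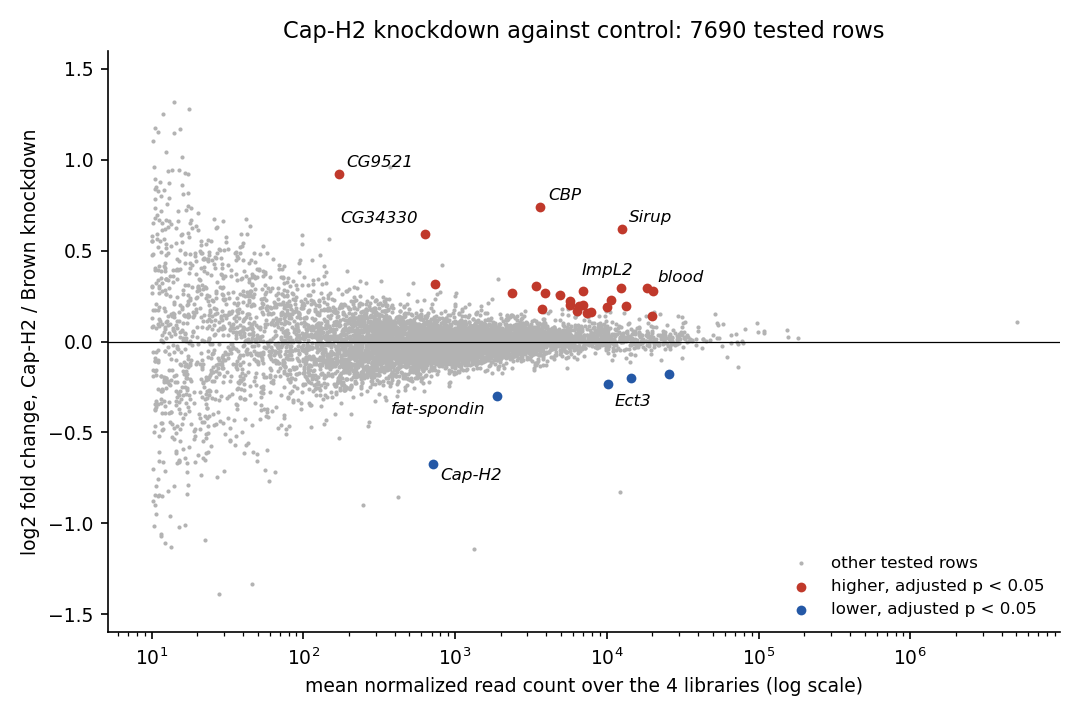
Log2 fold change of Cap-H2 over Brown knockdown against the mean normalized read count over the 4 libraries (log scale) for 7690 tested genes and element families, 1 point each. The 25 higher (red) and 5 lower (blue) calls at an adjusted p of 0.05 are drawn larger, and 3 rows beyond a log2 fold change of 1.6 in size lie outside the axis.

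CBP, a calcium-binding protein (FBgn0026144, chromosome X, 7337352 to 7342731), rose from 2739 ± 320 to 4558 ± 164 normalized reads (SD, n = 2 each), a log2 fold change of 0.74 (SE 0.06, limma adjusted p = 2.7e-06). Sirup, an assembly factor of mitochondrial complex II (FBgn0031971, chromosome 2L, 7998869 to 7999676), rose from 9933 ± 1263 to 15176 ± 568 (log2 fold change 0.62, SE 0.06, limma adjusted p = 1.5e-05). CG9521 and CG34330, both on the X chromosome, rose by 0.92 (SE 0.15) and 0.59 (SE 0.08) at lower levels, 120 and 504 normalized reads in the control. These 4 genes also differed between the control libraries, where library 2 exceeded library 1 on the log2 scale by 0.24 for CBP, 0.26 for Sirup, 0.52 for CG9521 and 0.30 for CG34330. Between the knockdown libraries library 2 was also higher, by 0.07 for CBP, 0.08 for Sirup, 0.18 for CG9521 and 0.09 for CG34330. With robust empirical Bayes, which lets unusually variable genes keep more of their own spread, the limma adjusted p was 0.18 for CBP and 0.53 for Sirup. With quantile normalization it was 0.12 for CG9521 and 0.060 for CG34330.

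ImpL2, a secreted protein that binds insulin-like peptides (FBgn0001257, chromosome 3L, 4224006 to 4236147), rose from 11216 ± 10.4 to 13750 ± 2.66 normalized reads (SD, n = 2 each; log2 fold change 0.29, SE 0.03, limma adjusted p = 2.3e-05). Fpps, the farnesyl pyrophosphate synthase, rose by 0.31 (SE 0.04), the transporter gene MFS3 by 0.28 (SE 0.03), and Cht2, a chitinase gene, by 0.32 (SE 0.06). Blood, an LTR retrotransposon family, rose from 16507 ± 677 to 20258 ± 166 (log2 fold change 0.30, SE 0.03, limma adjusted p = 6.8e-05), and its value stands for all copies that the counting assigned to blood. Cht2 did not pass without knockdown library 1 (adjusted p = 0.12) or with quantile normalization (adjusted p = 0.10). Exons of ImpL2 share 1651 of 2667 bp with CG46460 on the same strand, so reads there could not be assigned to either with certainty. The other 8 higher calls outside the glycolysis list were named after their values were seen. They were CG1703, Tspo, CG6330, Men, Sulf1, mtd, Dscam1 and RhoGAP71E, with log2 fold changes from 0.27 to 0.16. Exons of Tspo share 640 of 853 bp with rempA on the opposite strand. Without knockdown library 2 CG6330, Dscam1, RhoGAP71E and mtd did not pass (adjusted p from 0.092 to 0.36), nor did Men without knockdown library 1 (0.065) and mtd without control library 1 (0.19). With quantile normalization CG6330, Men, Sulf1, mtd, Dscam1 and RhoGAP71E did not pass (adjusted p from 0.17 to 0.37), and mtd, Dscam1 and RhoGAP71E did not with edgeR (from 0.058 to 0.080). Dscam1 and mtd also did not pass with median centring (0.055 and 0.061), with no minimum (0.076 and 0.10) or after a trend with exonic length was removed (0.19 and 0.18).

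Among the decreases, fat-spondin, a secreted matrix protein gene, fell by 0.30 on the log2 scale (SE 0.05), from 2075 ± 17.2 to 1686 ± 81.2 normalized reads (SD, n = 2 each, limma adjusted p = 0.0025). Ect3, which encodes a beta-galactosidase, fell by 0.23 (SE 0.03), GstS1, a sigma-class glutathione transferase, by 0.20 (SE 0.03) and regucalcin by 0.18 (SE 0.03). With quantile normalization the limma adjusted p was 0.054 for fat-spondin and 0.083 for regucalcin, and with median centring that of regucalcin was 0.055.

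Of the 14 genes of the glycolysis list tested, 8 rose in the knockdown, 12 passed adjusted over the list alone, and all 14 had a positive log2 fold change. Ldh, which converts pyruvate to lactate, rose from 18111 ± 1143 to 21966 ± 1218 normalized reads (SD, n = 2 each; log2 fold change 0.28, SE 0.04, limma adjusted p = 0.0019). Pgi, glucose-6-phosphate isomerase, rose by 0.26 (SE 0.04) and Ald1, aldolase, by 0.23 (SE 0.03). On the log2 scale library 2 minus library 1 was 0.13 in the control and 0.11 in the knockdown for Ldh. For Pgi these differences were 0.12 and 0.00, and for Ald1 -0.04 and -0.05. The remaining calls were Pfk, Gapdh2 and Eno, and Treh and Glyp, which encode trehalase and glycogen phosphorylase and act upstream of glycolysis. The list had a median log2 fold change of 0.17 and a camera adjusted p of 2.4e-24, against adjusted p = 0.52 with an estimated correlation. In 13 of the 14 both knockdown libraries exceeded both control libraries. With quantile normalization 5 of the 8 did not pass, with an adjusted p of 0.054 for Pgi, 0.076 for Pfk, 0.12 for Gapdh2, 0.15 for Glyp and 0.17 for Eno, and with robust empirical Bayes that of Ldh was 0.22. Eno also had 0.069 with edgeR, 0.071 with median centring and 0.076 with no minimum. Eno did not pass without control library 1 (adjusted p = 0.15) or without knockdown library 2 (0.14), nor Glyp without knockdown library 2 (0.087). Counts of Gapdh2 may miss reads shared with its near-identical paralog Gapdh1, since alignments that were not unique had a row of their own. Gapdh1 had a log2 fold change of 0.07 and did not pass.

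**Figure D2:**
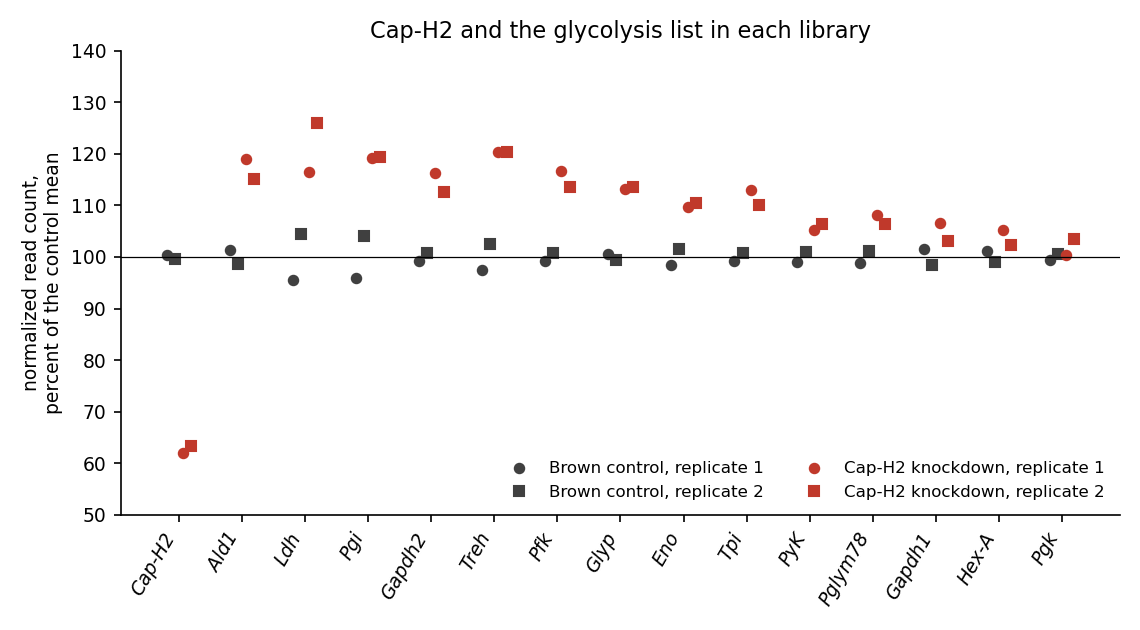
Normalized read count of Cap-H2 and the 14 tested genes of the glycolysis list in each library, as a percent of the mean of the Brown control libraries (100, line). Each point is a library, black for control, red for knockdown, circle for replicate 1 and square for replicate 2; Cap-H2 lies near 62.7 in the knockdown and the glycolysis genes lie above their control libraries for 13 of 14.

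The ecdysone response list, genes that answer to the steroid hormone of moulting, was also higher by camera (median log2 fold change 0.04, adjusted p = 0.0025), against adjusted p = 0.61 with an estimated correlation. After a trend with exonic length was removed the list had a median of 0.03 (camera adjusted p = 0.034). Of its 13 tested members 1 passed, ImpL2, and 1 did so adjusted over the list alone. Eip93F and br, transcription factors of the response, had log2 fold changes of 0.12 (SE 0.04, adjusted p = 0.37) and 0.08 (SE 0.03, adjusted p = 0.52). Eip93F stood at 0.18 without control library 1 and at 0.05 without control library 2, and br ranged from 0.03 to 0.13 when a knockdown library was left out. Without control library 2 the list's adjusted p was 0.074.

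Heat shock and chaperone genes passed camera as higher (median log2 fold change 0.08, adjusted p = 0.022). However, 0 of 17 members passed limma and 0 adjusted over the list alone (1 at an unadjusted p under 0.05). The count models edgeR and DESeq2 called 0, but DESeq2 gave most tested rows no adjusted p. With an estimated correlation the adjusted p was 0.82. Hsp67Bc had a log2 fold change of 0.42 (SE 0.22, adjusted p = 0.64), stv of 0.23 (SE 0.15, adjusted p = 0.71) and Hsp60A, the mitochondrial chaperonin, of 0.08 (SE 0.03, adjusted p = 0.55). The median of the list differed by 0.48 between the control libraries and by 0.30 between the knockdown libraries, with library 2 higher in both groups, against 0.08 between the groups. Hsp67Bc stood at 0.90 without control library 2 and at 0.77 without knockdown library 1, and stv at 0.50 without control library 2. Hsp60A stood at 0.04 without control library 1 and at 0.11 without control library 2. The direction of the list turned without control library 1 (median -0.13) and without knockdown library 2 (median -0.09). Its median was 0.34 without control library 2 and 0.21 without knockdown library 1.

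DNA replication genes were lower as a list by camera. The 31 tested members had a median log2 fold change of -0.08 and an adjusted p of 3.6e-05, against adjusted p = 0.61 with an estimated correlation. Of these, 0 passed limma over all genes and 2 adjusted over the list alone (7 at an unadjusted p under 0.05). The count models edgeR and DESeq2 called 0, but DESeq2 gave most tested rows no adjusted p. Mcm2, a subunit of the replicative helicase, stood at 2219 ± 0.824 normalized reads in the control and 2006 ± 0.767 in the knockdown (SD, n = 2 each; log2 fold change -0.15, SE 0.04, limma adjusted p = 0.20). RnrS, the small subunit of ribonucleotide reductase, had -0.13 (SE 0.04, adjusted p = 0.24) and Fen1, the flap endonuclease, -0.20 (SE 0.07, adjusted p = 0.43). Fen1 stood at -0.13 without knockdown library 2 and at -0.27 without knockdown library 1.

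Oxidative phosphorylation genes were lower by camera with a small median, -0.04 over 67 tested members (adjusted p = 0.00024, adjusted p = 0.55 with an estimated correlation). A negative value was found for 55 of the 67, and 0 passed limma over all genes or adjusted over the list alone (8 at an unadjusted p under 0.05). The count models edgeR and DESeq2 called 0, but DESeq2 gave most tested rows no adjusted p. The complex I subunit genes ND-B14.5A, ND-19 and ND-B12 had log2 fold changes of -0.22 (SE 0.07), -0.20 (SE 0.08) and -0.20 (SE 0.07), and that of ND-B14.5A was -0.14 without knockdown library 2 and -0.31 without knockdown library 1. Transcripts of this list are short, with a median exonic length of 871 bp against 2201 bp for all tested protein-coding genes, and after a trend with exonic length was removed the median was -0.02 (adjusted p = 0.034), as it was with median centring. Heterochromatin proteins passed as lower (17 tested, 0 passed over all genes or adjusted over the list alone, median -0.04, adjusted p = 0.026, adjusted p = 0.61 with an estimated correlation). The gene of HP1a (FBgn0003607) had -0.08 (SE 0.03), the histone methyltransferase gene G9a -0.10 (SE 0.04) and prod -0.12 (SE 0.06), with adjusted p from 0.55 to 0.61. In limma 3 members had an unadjusted p under 0.05. The count models edgeR and DESeq2 called 0, but DESeq2 gave most tested rows no adjusted p. The call of heterochromatin proteins ended without control library 1 (median -0.05, adjusted p = 0.082), without control library 2 (-0.04, 0.22), without knockdown library 1 (-0.02, 0.22) and with median centring (adjusted p = 0.055).

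**Figure D3:**
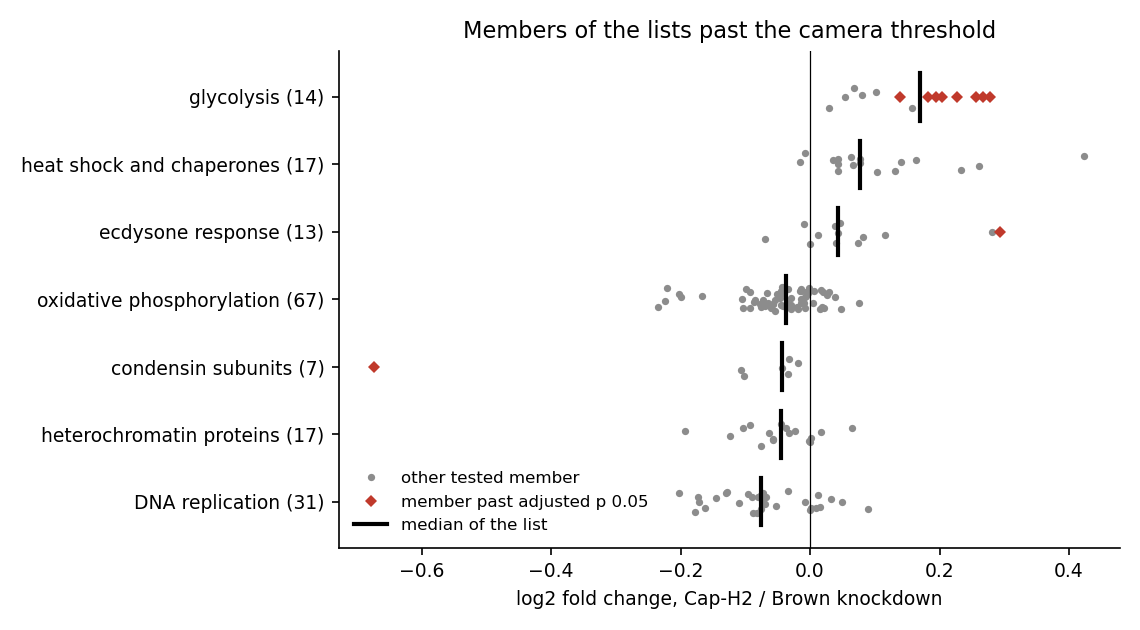
Log2 fold change of each tested member of the 7 lists past the camera threshold, with the number of tested members in parentheses. Grey points are members that did not pass, red diamonds members past an adjusted p of 0.05, and black bars list medians, which run from 0.17 for glycolysis to -0.08 for DNA replication.

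The remaining 28 lists did not pass camera, and 27 of them had no member past the limma threshold over all genes. Among lists on chromosome structure, the camera adjusted p was 0.068 for insulator and architectural proteins (median log2 fold change -0.03), 0.27 for cohesin and its regulators (-0.03), 0.75 for Polycomb group proteins (-0.01), 0.90 for homeotic and segmentation transcription factors, 0.90 for the nuclear envelope and lamina and 0.38 for dosage compensation (0.04). Insulator and architectural proteins passed as lower at a minimum of 50 (adjusted p = 0.035), with quantile normalization (0.035) and after the length correction (0.034). Adjusted over the list alone, 1 cohesin gene passed as higher, while 10 of the 11 tested cohesin genes had a negative value. None of the other lists on chromosome structure had a member past it. Among stress and defence lists it was 0.087 for unfolded protein and amino acid stress (0.01, 3 higher adjusted over the list alone), 0.90 for apoptosis and the p53 response (-0.00), 0.31 for antimicrobial and Toll/Imd genes (0.07) and 0.31 for RNA interference (0.05), with 0 past the threshold adjusted over the list alone in the last 3, and the first passed as higher after the length correction (0.046). In glutathione transferases and oxidative stress (adjusted p = 0.56, median 0.02), GstS1 passed over all genes and was the 1 member past it adjusted over the list alone.

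Mitosis genes had a camera adjusted p of 0.057 (39 tested, median -0.02), and passed as lower with quantile normalization (0.017), after the length correction (0.034), without control library 2 (0.024) and without knockdown library 1 (0.024). Signalling lists gave 0.56 for the JAK/STAT pathway, 0.24 for Notch targets (-0.09) and 0.90 for EGFR/ERK targets. Lists of cell maintenance gave 0.58 for cytoplasmic ribosomal proteins (0.00), 0.31 for mitochondrial ribosomal proteins (-0.02), 0.46 for the proteasome (-0.00), 0.076 for lipid synthesis and storage (0.04), 0.65 for laminins, integrins and the basement membrane, and 0.90 for the eye pigment pathway of the control target (0.00). Cytoplasmic ribosomal proteins passed as lower with quantile normalization (adjusted p = 0.015) and as higher after the length correction (7.8e-06) and without knockdown library 2 (0.049). Without knockdown library 2 Notch targets also passed as lower (0.034) and lipid genes as higher (0.023), and the proteasome list passed as lower without control library 1 (0.015). Adjusted over the list alone, 1 Notch target was lower, and in the matrix list 2 genes were higher and 4 lower. The others of these lists had 0.

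No list of cell type markers passed camera, though 2 of the 7 did in some alternatives. After the length correction the hemocyte (adjusted p = 0.013) and fat body (0.034) lists passed as lower, as did hemocyte markers with quantile normalization (0.017) and without knockdown library 2 (0.034), and fat body markers with median centring (0.049). The camera adjusted p was 0.46 for neuron, 0.31 for neuroblast, 0.64 for glia, 0.054 for hemocyte, 0.90 for muscle, 0.058 for fat body and 0.86 for testis and germline markers, and 0 members passed over all genes. Adjusted over the list alone, 1 hemocyte and 1 fat body marker were lower. The most abundant members stood in the control at 19971 ± 546 normalized reads for Syp, 9045 ± 259 for drpr, 8567 ± 13.2 for Tm1, 6190 ± 260 for srp, 1742 ± 37.2 for Syx1A, 1706 ± 8.20 for Apoltp and 379 ± 16.6 for mia (SD, n = 2 each). Their log2 fold changes were 0.00 for Syp, 0.06 for drpr, 0.03 for Tm1, -0.05 for srp, 0.08 for Syx1A, -0.15 for Apoltp and -0.02 for mia, and those of Syp, Tm1 and mia turned sign in some alternatives. Without control library 1 srp stood at -0.01 and drpr at 0.03, without control library 2 at -0.09 and 0.09, and with quantile normalization at -0.08 and 0.03. Median, mean and camera direction differed in sign for the homeotic, nuclear envelope, JAK/STAT, EGFR/ERK, matrix, neuron, muscle and testis lists, whose medians lay between -0.03 and 0.02.

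No chromosome arm passed camera. The median log2 fold changes were 0.00 for X (1337 tested), -0.00 for 2L (1343), -0.01 for 2R (1549), 0.01 for 3L (1480), -0.00 for 3R (1786), 0.01 for chromosome 4 (77) and 0.01 for 163 pericentromeric genes. By camera 0 of these 7 sets passed and 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.67. With an estimated correlation the count was 0 as well, and fry gave 0 after adjustment. The median and mean differed in sign for X, 2L and chromosome 4.

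The authors' deposited table held 32 rows at an adjusted p under 0.05, of which 27 were higher and 5 lower in the knockdown, and 22 at an adjusted p under 0.01. In the authors' deposited table Cap-H2 had a log2 fold change of -0.64 and an adjusted p of 4.6e-08, and ImpL2 of 0.27 with 2.3e-13. Between the authors' deposited table and the limma calls, 26 genes were shared. Cht2, Glyp, Ldh and mtd were called here alone, and Nipped-B, Psa, accord, copia, mam and unc-13 in the authors' deposited table alone, all 6 with the same direction here.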

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

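The exonic length correction, edgeR with a replicate block, and the block with an estimated correlation were chosen after seeing the data. Since the groups did not overlap in any of the 30 called genes, leaving out a library or changing the pseudocount could not turn their direction. Under the alternatives run, none of the 30 called genes reversed, and 11 passed under every alternative that gave them an adjusted p. Cap-H2 passed under all of these, between -0.69 and -0.65 (DESeq2 gave it no adjusted p, as for 6112 rows). Pseudocounts of 0.5 and 5, TMM and a minimum of 50 each called 30 genes, no minimum 27, median centring 27, edgeR 28 and the length correction 31. Quantile normalization called 14 (11 higher, 3 lower), robust empirical Bayes 59 (47 and 12), and DESeq2 45, with 41 higher. The causes were not tested. Leaving out a library gave 43 to 127 calls, 25 to 91 higher and 12 to 36 lower. The labels give both groups replicate numbers 1 and 2 but do not say that these pair the samples, and deviations of same-numbered libraries correlated at 0.046 over 4407 genes. With the replicate block 146 genes passed (102 and 44), and in edgeR with the block 160 (105 and 55). With the block 6 lists passed, with heterochromatin proteins at an adjusted p of 0.073, the condensin subunits without Cap-H2 at 0.055 and the heat shock list at 2.8e-12, and Hsp67Bc, Eip93F, Mcm2 and RnrS passed. Of the 35 lists 7 passed, 11 with quantile normalization, 13 after the length correction, and 0 with an estimated correlation (2 at an unadjusted p under 0.05), with fry (5 at an unadjusted p under 0.05) or with the block and an estimated correlation. With an estimated correlation camera uses the 2 residual degrees of freedom, and fry does not compare a list with other genes. Chromosome arms gave 0 in all alternatives. In the authors' deposited table there were 0 rows with an absolute log2 fold change of at least 1 at an adjusted p under 0.05.

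Values that changed sign without a library ranged over the 4 omissions from -0.0774 to 0.0091 (glu), -0.0414 to 0.0043 (Cap-D2), -0.0893 to 0.0037 (Cap-G), -0.0735 to 0.0083 (barr), -0.0574 to 0.9046 (Hsp67Bc), -0.0369 to 0.504 (stv), -0.0383 to 0.0463 (Syp), -0.1291 to 0.096 (mia) and, for the heat shock list, -0.1315 to 0.3425. Syp also turned to -0.0226 with quantile normalization and -0.0263 after the length correction, and Tm1 to -0.0017 with quantile normalization. With 2 libraries per group, simulated 1.2-fold changes were recovered in 65.7% of genes with a mean of at least 200, so smaller changes were often not detectable. The simulation left out spread between genes in their variability, so recovery in the real data can be lower.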

Other observations

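The sets and lists in this part, and the tests of within-group differences and of reads moved between rows, were chosen only after the results were seen. The tests of a trend with exonic length were also chosen after the data were seen, before the corrected values. Genes outside the naming rule are named here after their values were seen.

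Of 97 tested transposable element families, blood included, 61 had a positive log2 fold change in the knockdown. Both knockdown libraries lay above both controls in 33 families, against 14 below. All families as a set were higher by camera (median 0.06, adjusted p = 0.00011, adjusted p = 0.67 with an estimated correlation). LTR retrotransposons as a set were higher by camera (56 tested, median 0.05, adjusted p = 2.3e-05, adjusted p = 0.67 with an estimated correlation), with 1 family past limma's threshold over all rows and 8 higher adjusted over the list alone (13 at an unadjusted p under 0.05, 2 called by edgeR and 5 by DESeq2). Next to blood stood gypsy5 with a log2 fold change of 0.27 (SE 0.06, limma adjusted p = 0.059), accord with 0.15 (SE 0.03, adjusted p = 0.068) and invader4 with 0.14 (SE 0.03, adjusted p = 0.094). DESeq2 called accord (adjusted p = 0.0047) and invader4 (0.0086), and edgeR did not (0.089 and 0.095). With robust empirical Bayes gypsy5 (0.019), accord (0.0068) and invader4 (0.0088) passed limma, as gypsy5 did with median centring (0.047). Without control library 2 the log2 fold changes were 0.27 for gypsy5, 0.16 for accord and 0.18 for invader4. Lower values were 0.24 for gypsy5 without knockdown library 1, 0.10 for accord without knockdown library 2 and 0.09 for invader4 without control library 1. Non-LTR families had a camera adjusted p of 0.055, which was 0.0018 without control library 1 and 0.00077 without knockdown library 1, and DNA families of 0.72. Without knockdown library 2 the adjusted p was 0.15 for LTR (median 0.03) and 0.40 for all families (median 0.01).

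Genes of hypoxia, ERR and insulin signalling outside glycolysis passed camera as higher (14 tested, median 0.05, adjusted p = 0.00070, adjusted p = 0.24 with an estimated correlation), with 0 past limma's threshold, 3 at an unadjusted p under 0.05, 0 called by edgeR and 1 by DESeq2. Adjusted together with the 35 lists its p was 0.0013, without control library 1 the adjusted p was 0.053, and after the length correction the median was 0.03 (adjusted p = 0.0038). Within it scyl and chrb, inhibitors of TOR signalling, had log2 fold changes of 0.13 (SE 0.03, limma adjusted p = 0.096) and 0.10 (SE 0.03, adjusted p = 0.27). Amino acid, folate and pentose phosphate enzymes (camera adjusted p = 0.099), where Men, a malic enzyme, rose by 0.20 (SE 0.03, limma adjusted p = 0.011), and the mevalonate pathway (camera adjusted p = 0.099), where Fpps alone of 7 passed, were not called. Histone rows, which a poly(A) library hardly captures, held 916 and 919 reads in the control libraries and 709 and 752 in the knockdown libraries.

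The higher genes of the glycolysis list were weighed against 2 technical explanations. A trend with exonic length was small, with median log2 fold changes from -0.02 in the shortest genes to 0.02 in the longest. Its removal could therefore hardly change the list's median, which was 0.17 before and 0.1757 after. The size of the trend, rather than this test, argues against length for this list. The median of the list differed by 0.023 between the control libraries and by -0.0123 between the knockdown libraries, which does not decide whether cultures differed along this axis, since the labels do not say that the libraries of a group came from separate cultures. A difference between cultures, such as one in growth or medium, therefore cannot be told apart from an effect of Cap-H2 knockdown. Cap-H2 knockdown stays among the open explanations, and no mechanism was tested.

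Oxidative phosphorylation genes were lower by a median of -0.04, and the median differed within groups by at most -0.0074, which leaves a difference between cultures open for the same reason. Median log2 fold changes by exonic length ran from -0.02 in the shortest genes to 0.02 in the longest. Median deviations from the gene means went from -0.02 to 0.02 in knockdown library 2 and from 0.01 to -0.01 in both control libraries, while knockdown library 1 had -0.0010 in the shortest and -0.0037 in the longest. After the length trend was removed the median was -0.0154 (adjusted p = 0.034), less than before but still past the threshold. Length bias and an effect of Cap-H2 knockdown cannot be told apart for this list, because its members are short and the correction moves the median by more than the part that is left.

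Element families differed within the knockdown group by a median of 0.0675, as much as the 0.06 between the groups, so for their median a difference between libraries is a candidate explanation. For blood the largest within-group difference was -0.0837 against 0.30 between the groups, and for copia 0.0326 against 0.11. These values do not decide the question, because both families were picked for their difference between the groups. A difference between cultures also stays open for both. Copia had an adjusted p of 0.62 by limma, 8.0e-05 with robust empirical Bayes, 2.3e-05 by edgeR and 0.0047 by DESeq2. Quantile normalization, which equalizes the most abundant row of each library, gave copia a log2 fold change of 0.00. Element rows differed by 400107 normalized reads between the groups (within-group SD 77001 and 83245, n = 2 each), and copia, which makes up most of them, had 4774170 and 4883440 in the control and 5157640 and 5247370 in the knockdown. Alignments that were not unique differed by -192476 (knockdown minus control), and the sum with element rows by 207630 against a summed within-group SD of 426998. Whether reads moved from the not-unique row to the element rows therefore cannot be told apart from higher element levels.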
